A study of Bos indicus with 8 samples.

How the data were processed

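Cumulus-oocyte complexes from slaughterhouse ovaries were cultured for 6 h in a buffered medium with 10% serum, 0.2 mM pyruvic acid, oestradiol and recombinant FSH, with or without 3 mM adenosine, per the labels' protocols. Total RNA of the cumulus cells was amplified in 2 rounds of T7 transcription and labelled chemically with Cy3 or Cy5, per the labels. Amplification of this kind can favour the 3' ends of transcripts, and whether a probe's response depended on its place in the transcript was not tested, since no probe positions were given. The labels count biological replicates and nothing in them says that pools came from separate animals, so the p-values measure the spread between these pools.

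The deposited scanner files hold, per the file headers, the mean foreground intensity and the median local background of each of 45220 spots at 532 nm (taken as Cy3) and 635 nm (taken as Cy5), with neither background subtraction nor normalization. The software that quantified the spots is not given in the sources used here, and no saturation flag was used. The highest probe intensities lay between 36038 and 40104 on each array and channel. The series also has the authors' normalized log2 values in a value table and in a table with control spots. Against the scanner values, the value table held log2 ratios of adenosine over control on every array (slope on the ratios of bright probes between 0.929 and 1.03), and the normalized table Cy5 over Cy3, since turning the sign of the arrays with adenosine in Cy3 made the tables equal to within 5e-06. Array medians of the authors' value table lay between 0.00566 and 0.0524, and those of the normalized table between -0.0498 and 0.0394. The scale and direction were thus settled, and how the authors normalized and centred the arrays is not given in the sources used here.

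Background was corrected with normexp and an offset of 50, which shrinks the ratios of dim probes, and each array was normalized by loess with the 1426 control and empty spots at weight 0, in limma 3.58.1 under R 4.3.3. Ratios were turned to adenosine over control and the 2 arrays of a replicate number averaged, which cancels a dye effect of equal size on both slides. Each slide held 1 orientation, so a dye effect that differed between the slides does not cancel, stays in all 4 pair means alike and is not measured by their spread. A probe was kept when its foreground exceeded the mean plus 2 SD of the 153 negative control spots of its channel and array, in both arrays of at least 3 of the 4 pools of either group. The mean ratio of the 4 pool pairs was tested against 0 with lmFit and eBayes, with Benjamini-Hochberg adjustment over 31948 probes and a threshold of 0.05. Values are log2 ratios with the SD between pool pairs. Levels per pool used single-channel values after loess and Aquantile scaling.

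Same-numbered arrays were taken as the same RNA from the labels, and the data were checked for it. Deviations from the mean of each orientation correlated between 0.763 and 0.925 across probes for arrays of the same number, and 8 of 8 arrays correlated best with their own number. Turned ratios correlated between 0.894 and 0.913 within a pair, between 0.715 and 0.86 across pairs of opposite orientation, and between 0.799 and 0.931 across pairs of the same orientation, so a shared slide and orientation also made arrays agree. Probes are not independent replicates in these correlations.

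Probe names came from the platform's annotation, which dates from the array's design. Of the probes 21790 had 1 gene symbol, 0 had several and 22004 had none, and 12538 of 15229 symbols were found in the gene table of a Bos indicus assembly, which was used for names only. No coordinates were used. A gene was read from its brightest kept probe. Among 1096 genes with several changed probes, 50 had probes that changed in opposite directions. Named probes were called more often (42.3%) than unnamed ones (31.3%).

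Before the data were examined, 34 gene lists were fixed, for cumulus function, signalling, metabolism, stress, cell cycle and the markers of other cell types, together with the tests, the alternatives and the genes to name. These were the 12 largest rises and 12 largest falls among named genes with an adjusted p under 0.05 and the same sign in all 4 pairs, 14 genes of cumulus expansion, FSH response and adenosine handling, and up to 4 members of each list with the smallest p. Fewer members were drawn from lists that did not pass camera, so that number followed the results, and not every member drawn is named below. Genes named outside this rule are said to be. Lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. With an estimated correlation camera takes its degrees of freedom from the 4 pool pairs, and with a preset one from the number of genes. The former is thus harder to pass even for lists whose genes are not correlated. A list of 1 cell type can hold genes that cumulus cells express.

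The functions were tested on simulated intensities made from the real probes, with a dye bias and each probe's own spread between pairs. Of 66 probes changed by 2 on the log2 scale, 67 by 1 and 67 by 0.5, 93.9%, 62.7% and 19.4% were called in the simulated comparison of 4 pool pairs over 29563 kept probes, all with the right sign, and 7.52% of the calls were false. A change of 2 was estimated at 1.48 in the median. The fit with a replicate block called 62.7% of the changes of 0.5, with 43.3% of its calls false. A simulated list of 20 genes shifted by 0.8 had a mean of 0.63 and passed camera with either correlation, and an unshifted list passed with neither. The spread of each simulated probe was drawn independently, so the genes of a simulated list were not correlated. In the data the lists that passed had estimated correlations between 0.0412 and 0.493, for which the simulation tests neither camera setting. It also changed few probes, against 37.1% called in the data.

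Alternatives were no background correction, an offset of 0, Aquantile after loess, median centring, the authors' values, no filter, a stricter filter (above the detection level on every array in both groups), a replicate block with a dye term, no replicate block on single-channel values, trend and robust variances, each dye orientation alone, each replicate left out, thresholds with a 2-fold or 1.5-fold change, and the mean of a gene's probes. Control spots other than the negative controls entered no comparison.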

Results

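Gene expression was measured in bovine cumulus cells, the somatic cells that surround the oocyte, on 8 two-colour oligonucleotide arrays. The sample labels give the species as Bos indicus. Cumulus-oocyte complexes from ovarian follicles of 3 to 6 mm were cultured for 6 h with follicle-stimulating hormone (FSH) at 0.5 µg/ml and oestradiol at 1 µg/ml, with or without 3 mM adenosine, a purine nucleoside. RNA came from 4 adenosine pools and 4 control pools, each labelled as holding 10 per pool. Every adenosine pool was hybridised against the control pool of the same replicate number on 2 arrays with the dyes exchanged, which gives 4 pool pairs. The arrays carried 43794 probes, and 31948 of them, covering 12320 named genes, passed the detection filter. On 7 of the arrays between 71.1% and 87.4% of the probes exceeded the detection level in each channel. On the array of pool pair 3 with adenosine in Cy3 the shares were 45.4% for adenosine and 41.3% for control, and its negative control spots were more widely spread (SD 15.1 in Cy3 against at most 3.91 on the others). The number of arrays limits the precision.

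The comparison asked how adenosine changed the transcripts of cumulus cells during the first hours of culture with FSH. No sample from before culture is among the arrays. A fall or rise therefore means a lower or higher level with adenosine than in control, and not a change over time. Genes of the cumulus matrix, of EGF-like and cAMP signalling and of the unfolded protein response were lower with adenosine as groups, and ribosomal protein and respiratory chain genes were higher, by camera with a preset correlation. None of these lists passed with an estimated correlation (adjusted p between 0.431 and 0.489), a setting whose degrees of freedom come from the 4 pool pairs alone. HAS2, the enzyme that makes the hyaluronan of the expanding cumulus, fell 27.2-fold (log2 ratio -4.77 ± 0.47, SD, n = 4 pool pairs, adjusted p = 0.000672), with 7 of its 8 adenosine channel values above the detection level and a log2 ratio of -6.34 with an offset of 0. Among 12320 genes 2671 rose and 2558 fell, and 7091 did not pass. Counted by probe, 11847 changed at an adjusted p under 0.05 in limma, 5955 higher and 5892 lower with adenosine. The larger changes were mostly falls: 261 genes fell by over 4-fold and 8 rose by over 4-fold, while 87 fell by over 8-fold and 0 rose by that much. Without replicate 4 the count was 7399 of the 20765 probes that the filter kept on 3 pairs, and 6568 of the 31948 kept over all 4 pairs. An unpaired fit of single-channel values, with no replicate block, called 7497 probes, and median centring in place of loess gave 4709 higher and 7511 lower.

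The steepest fall was that of C27H8orf4, at 88.0-fold (log2 ratio -6.46 ± 1.12, SD, n = 4). BMP2, a growth factor of the TGF-beta family, followed with -6.25 ± 0.53, and PLIN2, a coat protein of lipid droplets, with -5.82 ± 0.19. COBLL1 had a log2 ratio of -5.81 ± 0.53, and the chemokine receptor CXCR4 -5.71 ± 0.46. GEM, a small GTPase, had a log2 ratio of -5.37 ± 0.82, with -3.84 on the arrays with adenosine in Cy5 and -6.89 on those with adenosine in Cy3. SLC39A8, a zinc transporter, stood at -5.27 ± 0.34 (-4.24 and -6.31 in the respective orientations), and GCH1, the first enzyme of tetrahydrobiopterin synthesis, at -5.24 ± 0.20. AMIGO2, a cell adhesion protein, gave -5.10 ± 0.44, HK2, a hexokinase, -4.92 ± 0.30, and JMJD1C, a member of a histone demethylase family, -4.82 ± 0.16. The mean of a gene's kept probes gave smaller falls for COBLL1 (-2.89), GCH1 (-2.70) and HK2 (-3.68). HAS2 completed the 12 largest falls, whose adjusted p lay between 0.000122 (PLIN2) and 0.00182 (C27H8orf4).

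Rises were smaller. GATM, an enzyme of creatine synthesis, rose 5.95-fold (log2 ratio 2.57 ± 0.65, SD, n = 4, adjusted p = 0.00416). MAN1A1, a mannosidase that trims N-glycans, rose by 2.44 ± 0.37. DDAH1, which degrades methylated arginines, rose by 2.16 ± 0.46, and MSRB3, a methionine sulfoxide reductase, by 2.08 ± 0.39. DDO, a D-aspartate oxidase, had a ratio of 1.96 ± 0.43, and THRA, a thyroid hormone receptor, 1.95 ± 0.24. CETN3, a centrin, had 1.92 ± 0.51, and NRP1, a co-receptor for semaphorins and VEGF, 1.90 ± 0.39. With the mean of a gene's kept probes the ratios were 1.46 for MAN1A1, 1.16 for DDAH1, 1.05 for MSRB3 and 1.24 for NRP1. The lysozyme genes LYSB (2.43 ± 1.05) and LYZ2 (2.22 ± 0.92) are close paralogs, so their probes may share signal, and LYSB did not pass without replicate 3 (2.12, adjusted p = 0.0511, with a range of 0.000345 to 0.193 over the alternatives). With the probes kept over all 4 pairs, neither passed without replicate 2 or 4. TRIM2 rose by 2.38 ± 0.40 on its brightest probe, but a dimmer probe of the same gene fell by 1.16 (adjusted p = 0.00193), and the mean of its probes did not pass (0.26). A probe named for the microRNA gene MIR2299 rose by 2.01 ± 0.20, and which transcript it reads is not given in the sources used here.

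**Figure D1:**
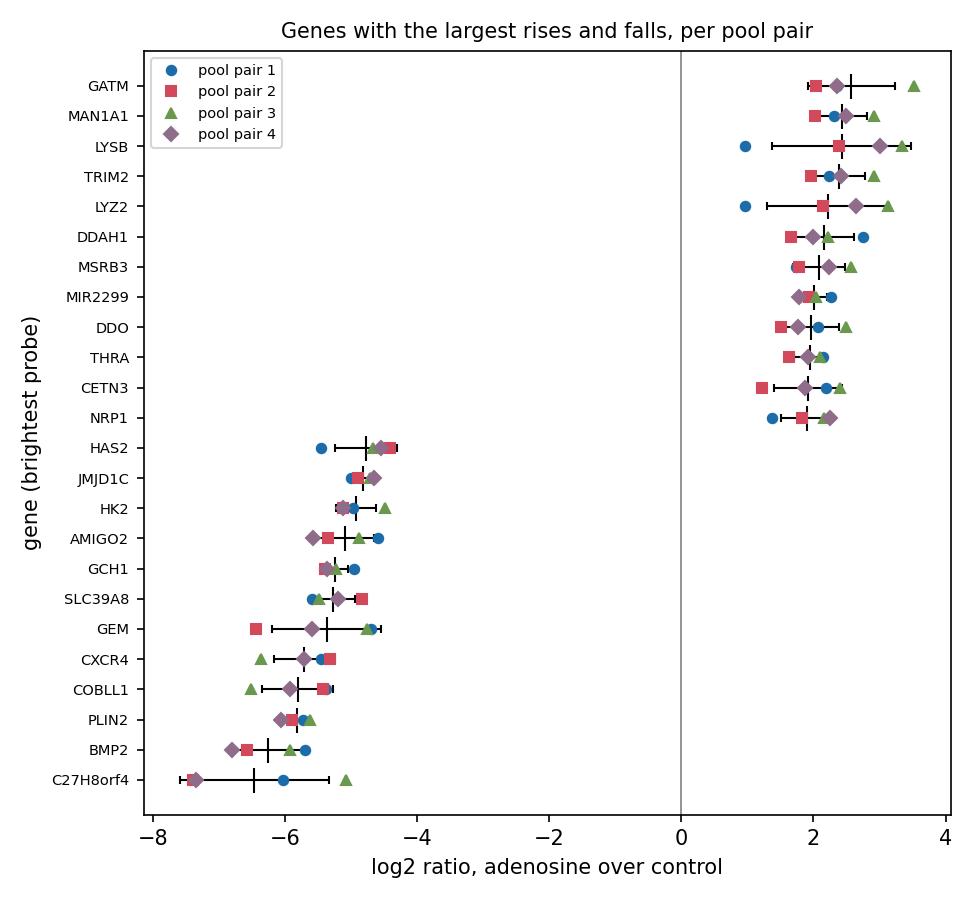
Log2 ratio of adenosine over control (x axis) for the 12 genes with the largest rises and the 12 with the largest falls (y axis). Coloured symbols are the 4 pool pairs, each the mean of 2 arrays with the dyes exchanged, and the black tick and bar are their mean and SD. All 4 symbols lie on the same side of 0 for every gene shown, and the falls reach -6.46 (C27H8orf4) while the rises end at 2.57 (GATM).

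Genes of the cumulus expansion matrix were lower as a group by camera with a preset correlation (adjusted p = 0.0375), but not with an estimated one (adjusted p = 0.489 with an estimated correlation). Of 16 measured members 8 fell, 3 rose and 5 did not pass, with the same counts adjusted over the list alone, and the list mean was -1.14 ± 0.17 (SD over pairs, n = 4). Besides HAS2, the protease ADAMTS1 had a log2 ratio of -4.06 ± 0.66, TNFAIP6, which links proteins to hyaluronan, -3.31 ± 1.10 (adjusted p = 0.0507 without replicate 4 over all kept probes), and the proteoglycan SDC4 -2.21 ± 0.43. PTGS2, the inducible prostaglandin synthase, with 1 of its 3 probes kept, fell by 0.85 ± 0.19 (adjusted p = 0.00321). Its probe was dim, with mean log2 levels of 6.70 with adenosine and 7.55 in control. The size of its fall depended on the background (-0.67 without background correction, -1.45 with an offset of 0). PTX3, a matrix pentraxin, had a ratio of -0.42 ± 0.41 and did not pass (adjusted p = 0.13), although it did without replicate 2 (-0.58, adjusted p = 0.0379) and in the fit with a replicate block (adjusted p = 0.0287, with a range up to 0.602 over the alternatives). The list did not pass without replicate 3 (-1.11, adjusted p = 0.0593), under median centring (adjusted p = 0.117), without the detection filter (adjusted p = 0.0507), on the arrays with adenosine in Cy3 (adjusted p = 0.0633), with the mean of a gene's probes (adjusted p = 0.0516) or in pool pairs 1 and 2 alone (adjusted p = 0.082), and the lowest adjusted p of camera over the alternatives was 0.00727. A list of hexosamine and UDP-sugar synthesis, which holds HAS2 beside the enzymes that supply its sugars, passed too (camera adjusted p = 0.0265, adjusted p = 0.463 with an estimated correlation). Without the hyaluronan synthases, left out after their values were seen, it did not (11 measured, mean -0.72 ± 0.09, median -0.31, camera adjusted p = 0.0553). Of 13 measured genes for hexosamine and UDP-sugar synthesis, HAS2 among them, 8 fell, 1 rose and 4 did not pass, again with the same counts adjusted over the list alone. GFPT2, which starts the hexosamine pathway, fell 12.5-fold (-3.64 ± 0.63), UAP1 6.31-fold (-2.66 ± 0.30) and PGM3 1.83-fold (-0.87 ± 0.13). UGP2, which makes UDP-glucose and is named after its value was seen as the member that rose, had a ratio of 0.99 ± 0.37. That list had a mean of -0.98 ± 0.11 and did not pass without replicate 1 (-1.07, adjusted p = 0.123) or replicate 2 (-1.13, adjusted p = 0.0687), of which only the former held with the probes kept over all 4 pairs (-0.93, adjusted p = 0.0797). Nor did it pass with the stricter filter (adjusted p = 0.197), with the mean of a gene's probes (adjusted p = 0.0541) or in pool pairs 3 and 4 alone (adjusted p = 0.108), and the lowest adjusted p of camera over the alternatives was 0.00213.

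Genes of EGF-like and of cAMP signalling were also lower (for either list camera adjusted p under 0.05, and adjusted p = 0.431 with an estimated correlation). In the list of EGF-like ligands and feedback genes of the EGFR-MAPK pathway 13 of 15 measured members fell, 1 rose and 1 did not pass, unchanged when adjusted over the list alone. The list mean was -0.95 ± 0.09 (camera adjusted p = 3.93e-05). The ligand AREG fell (-2.59 ± 0.89, adjusted p = 0.00868), and 3 of its 8 adenosine channel values were above the detection level against 8 of 8 in control, so that the size of its fall depended on the background (-1.95 without background correction, -5.04 with an offset of 0). It did not pass without replicate 4 over all kept probes (-2.49, adjusted p = 0.0532). The ligand HBEGF had a ratio of -0.73 ± 0.09, with 4 of 8 adenosine channel values above the detection level and -1.89 with an offset of 0. BTC, an EGF-like ligand named after its value was seen as the member that rose, had a ratio of 1.28 ± 0.28 (adjusted p = 0.00314), or 0.68 as the mean of its 3 kept probes. The MAPK feedback gene SPRY2 had a ratio of -3.29 ± 0.38 and IER3 -1.62 ± 0.09. EREG had no probe with its symbol. Of 17 measured cAMP-CREB response genes 10 fell and 7 did not pass, also when adjusted over the list alone, with a mean of -1.11 ± 0.34 (camera adjusted p = 0.00161). NR4A1, an orphan nuclear receptor, had a ratio of -3.33 ± 0.27, with -2.24 on the arrays with adenosine in Cy5 and -4.42 on those with adenosine in Cy3. The kinase SGK1 fell 9.64-fold (-3.27 ± 0.42), and RGS2, a regulator of G protein signalling, 4.34-fold (-2.12 ± 0.37), and with an offset of 0 the ratios were -4.33 and -3.11. INHBA, a subunit of activins and inhibins with a bright probe, fell by 0.98 ± 0.15, but stood at -0.03 on the arrays with adenosine in Cy5 alone (adjusted p = 0.862, the highest over the alternatives, against a lowest of 5.52e-05).

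Immediate early genes, which are transcribed within minutes of a stimulus, had a mean of -1.16 ± 0.76 over 18 measured members. Of these 7 fell, 1 rose and 10 did not pass, or 9, 1 and 8 adjusted over the list alone. The pool pairs differed in this list, with means of -0.51 in pair 1, -1.88 in pair 2, -0.50 in pair 3 and -1.75 in pair 4. FOSL1, a subunit of AP-1, fell 13.5-fold (-3.76 ± 0.24), and MYC 7.28-fold (-2.86 ± 0.51). KLF6 fell by 0.68 ± 0.13, while SRF, the serum response factor, rose by 0.29 ± 0.05. The camera adjusted p = 0.0348 became adjusted p = 0.809 with an estimated correlation, the highest over the alternatives, against a lowest of 0.00669. The list did not pass without replicate 2 (-0.92, adjusted p = 0.131) or 4 (-0.97, adjusted p = 0.0888), with the stricter filter (adjusted p = 0.0659), with adenosine in Cy3 alone (adjusted p = 0.053) or with the mean of a gene's probes (adjusted p = 0.0544).

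Genes of the unfolded protein response and ATF4 targets fell in 17 of 24 measured cases, 1 rose and 6 did not pass, with 18 falls adjusted over the list alone. The mean was -1.29 ± 0.17 (camera adjusted p = 3.93e-05, adjusted p = 0.431 with an estimated correlation). PSAT1, an enzyme of serine synthesis, fell 25.3-fold (-4.66 ± 0.57), and the endoplasmic reticulum co-chaperone DNAJB9 14.7-fold (-3.88 ± 0.50). DNAJC3 had a ratio of -1.11 ± 0.12, and EDEM1, which directs misfolded glycoproteins to degradation, -0.80 ± 0.08. The member that rose was SLC7A11, a cystine transporter named after its value was seen (0.24 ± 0.10), which did not pass under median centring (0.02, adjusted p = 0.757), in the unpaired fit or without replicate 2, 3 or 4.

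Ribosome biogenesis factors and ribosomal proteins moved in opposite directions. Of 25 measured biogenesis factors 17 fell, 1 rose and 7 did not pass, with 17 falls and 2 rises adjusted over the list alone, and the mean was -0.66 ± 0.06 (camera adjusted p = 3.93e-05, adjusted p = 0.431 with an estimated correlation). WDR43 had a ratio of -2.02 ± 0.09, UTP15 -2.07 ± 0.28, GNL3 -0.95 ± 0.11 and the RNA helicase DDX21 -0.89 ± 0.06. The member that rose was NHP2, named after its value was seen (0.47 ± 0.23), which did not pass under median centring (0.13, adjusted p = 0.415), in the unpaired fit or without replicate 3 or 4. Of 39 measured ribosomal protein genes 33 rose, 0 fell and 6 did not pass, with 35 rises adjusted over the list alone, and the mean was 0.72 ± 0.09 (camera adjusted p = 1.79e-10, adjusted p = 0.431 with an estimated correlation). RPL30 rose by 0.83 ± 0.07, RPL34 by 0.91 ± 0.09, RPL15 by 0.96 ± 0.10 and RPL5 by 0.72 ± 0.06, over both orientations. The size of this rise depended on the dyes: the list mean was 1.18 on the arrays with adenosine in Cy5 and 0.27 on those with adenosine in Cy3 (camera adjusted p = 0.0566, with a range of 1.19e-12 to 0.431 over the alternatives), and on the latter RPL5 stood at -0.19, RPL34 at 0.17 and RPL15 at 0.28. The 16 members with a mean log2 brightness under 13 had means of 0.81 and 0.83 in the respective orientations, and the 23 brighter ones 1.44 and -0.12, or 0.66 ± 0.11 (SD over pairs, n = 4) over both.

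**Figure D2:**
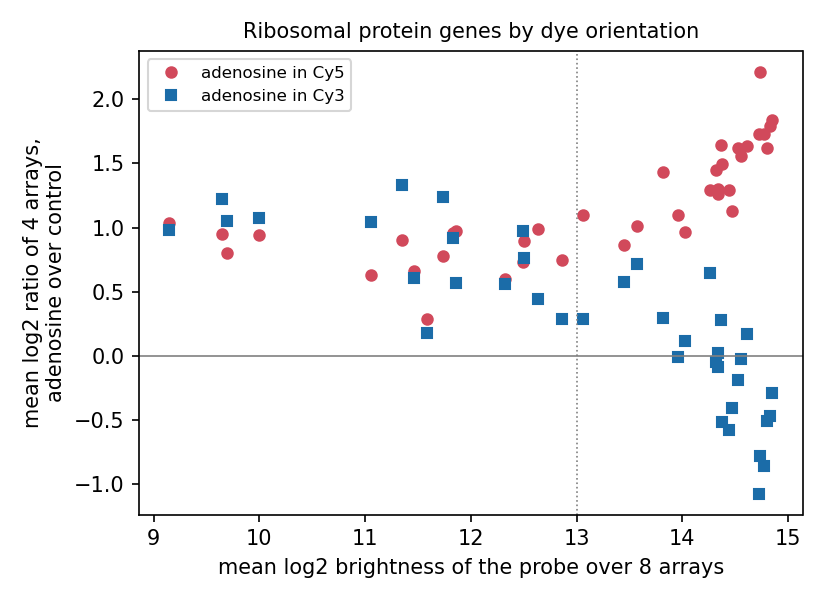
Mean log2 ratio of adenosine over control (y axis) of 39 ribosomal protein genes against the mean log2 brightness of the probe over 8 arrays (x axis). Circles are means of the 4 arrays with adenosine in Cy5, squares those of the 4 arrays with adenosine in Cy3, and the dotted line marks a brightness of 13. Below the line all 16 genes lie above 0 in both orientations, and above it the orientations part, with means of 1.44 and -0.12.

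Oxidative phosphorylation genes rose in 29 of 34 measured cases, 1 fell and 4 did not pass, with 31 rises adjusted over the list alone. The mean was 0.61 ± 0.09 (camera adjusted p = 9.74e-09, adjusted p = 0.431 with an estimated correlation). Of the complex I subunits NDUFB3 rose by 0.78 ± 0.04 and NDUFS3 by 0.80 ± 0.07, and ATP5O, a subunit of the ATP synthase, rose by 1.12 ± 0.12 but did not pass in the unpaired fit. Of the members, 8 had a brightness of 13 or more, with means of 0.92 with adenosine in Cy5 and 0.02 with adenosine in Cy3, and 26 were dimmer, with means of 0.59 and 0.72. The member that fell was CYCS, cytochrome c, at -1.27 ± 0.18. Over the alternatives the list mean lay between 0.32 and 0.67. Under median centring NDUFB3 stood at 0.42, NDUFS3 at 0.44, ATP5O at 0.77 and CYCS at -1.55.

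Glycolysis as a list did not pass camera (mean -0.36 ± 0.27, median 0.07, set test downward, camera adjusted p = 0.595): of 18 members 2 rose, 4 fell and 12 did not pass, also when adjusted over the list alone. Of its members HK2 and SLC2A1, a glucose transporter, fell, the latter 6.28-fold (-2.65 ± 0.29). Of 19 hypoxia-inducible genes 3 rose and 5 fell (mean -0.40 ± 0.19, adjusted p = 0.381), with NDRG1 at -2.35 ± 0.25 and KDM3A, a histone demethylase, at -1.58 ± 0.05. The 19 oxidative stress genes went both ways, 8 up and 5 down, or 9 and 5 adjusted over the list alone. Their mean was -0.05 ± 0.16, their median 0.32 and the direction of the set test upward (adjusted p = 0.556). Within that list SRXN1, which repairs peroxiredoxins, fell 15.3-fold (-3.94 ± 0.09), and the thioredoxin reductase TXNRD1 7.87-fold (-2.98 ± 0.16). Of 20 genes for cholesterol synthesis and uptake 3 rose and 9 fell (mean -0.40 ± 0.21, adjusted p = 0.272), among them CYP51A1 (-1.41 ± 0.10) and NSDHL (-1.07 ± 0.19).

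Genes that handle adenosine itself showed no common shift: of 21 measured genes for adenosine receptors, transport and metabolism 7 rose, 4 fell and 10 did not pass. Their mean was -0.02 ± 0.06, their median 0.00 and the direction of the set test upward (adjusted p = 0.595). The receptor ratios were 0.03 ± 0.02 for ADORA1, -0.03 ± 0.08 for ADORA2A, -0.03 ± 0.16 for ADORA2B and 0.00 ± 0.08 for ADORA3 (adjusted p between 0.372 and 0.989). ADORA2A passed under median centring (-0.28, adjusted p = 0.00841, with a range up to 0.959 over the alternatives), and ADORA3 was above the detection level in 3 of 8 adenosine channel values. ADK, the adenosine kinase, rose by 0.63 ± 0.17 (adjusted p = 0.00499), but under median centring it stood at 0.27 and did not pass (adjusted p = 0.072, the highest over the alternatives, against a lowest of 3.27e-05). ADA, the adenosine deaminase, stood at 0.06 (adjusted p = 0.104), and passed under median centring (0.10), with an offset of 0 (0.21) and with adenosine in Cy5 alone (0.14). The probes of ADORA1, ADORA3 and ADA were dim, with mean log2 levels between 6.15 and 6.30 in either group. The median over all genes was 7.13. At such levels the offset shrinks ratios toward 0, so a change of these genes may have been missed. The adenylate kinase AK1 rose by 0.38 ± 0.05. AK3L1 fell by 1.74 ± 0.32 on its brightest probe, but another of its probes rose by 0.62 (adjusted p = 0.0258), and the mean of its probes did not pass (-0.19). Nucleotide synthesis genes numbered 7 up and 2 down among 19 (mean 0.14 ± 0.08, adjusted p = 0.556), with UMPS, of the pyrimidine pathway, at -1.38 ± 0.16 and the thymidylate synthase TYMS at 1.12 ± 0.27. Of the dimmer TYMS probes 1 fell by 0.20 and 1 rose by 0.41. Of 18 genes of the methionine cycle 3 rose and 6 fell (mean -0.24 ± 0.05, adjusted p = 0.601). AHCY, which removes the adenosine-containing product of methylation, rose by 0.96 ± 0.13 but did not pass in the unpaired fit, and MTHFD2, a mitochondrial folate enzyme, had a ratio of -1.74 ± 0.12. In the AMPK pathway 3 of 11 members fell and 0 rose (mean -0.40 ± 0.05, adjusted p = 0.276), led by the regulatory subunit PRKAG2 (-3.07 ± 0.39). Leaving out a replicate moved this mean as far as -0.62 where the filter kept fewer members, and to between -0.42 and -0.38 with the same members.

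Granulosa and cumulus identity genes did not pass camera as a list (5 of 16 rose, 3 fell, or 5 and 4 adjusted over the list alone, mean -0.11 ± 0.05, adjusted p = 0.859), nor did FSH-responsive and steroidogenic genes (4 of 14 rose, 5 fell, or 5 and 6 adjusted over the list alone, mean -0.21 ± 0.17, adjusted p = 0.622). FSHR, the FSH receptor, rose 1.65-fold (0.72 ± 0.30, adjusted p = 0.0148), which did not pass under median centring (0.38, adjusted p = 0.105), without replicate 1 or 4 over all kept probes (0.69 and 0.79), or in the unpaired fit (adjusted p = 0.345, the highest over the alternatives, against a lowest of 0.000382). INHA, the inhibin alpha subunit, rose by 0.91 ± 0.20. CYP19A1, the aromatase, had a ratio of -0.31 ± 0.38 and did not pass (adjusted p = 0.211), although it did without replicate 3 (-0.49, adjusted p = 0.0227, with a range up to 0.772 over the alternatives), and a dimmer probe of the gene passed (-0.47, adjusted p = 0.0106). Of 13 SMAD targets and oocyte-regulated genes 2 rose and 6 fell (mean -0.63 ± 0.16, adjusted p = 0.179, and 0.0352 in the unpaired fit, with a range of camera values up to 0.489 over the alternatives), with BAMBI, a decoy receptor for the TGF-beta family, down 12.2-fold (-3.60 ± 0.24). Among 16 extracellular proteases and their inhibitors 5 rose and 6 fell (mean -0.72 ± 0.15, adjusted p = 0.428), and TIMP2 fell by 3.00 ± 0.32.

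The remaining response lists did not pass camera with a preset correlation either. Of 16 p53 and DNA damage genes 3 rose and 6 fell, or 3 and 7 adjusted over the list alone (mean -0.77 ± 0.28, adjusted p = 0.271), with PLK2 at -3.80 ± 0.42 and TP53INP1 at -1.18 ± 0.11. Of 15 heat shock genes 2 rose and 5 fell, or 2 and 6 adjusted over the list alone (mean -0.36 ± 0.13, adjusted p = 0.452), with the co-chaperones BAG3 at -2.20 ± 0.46 and HSPH1 at -1.78 ± 0.51. Of 14 apoptosis regulators 3 rose and 5 fell (mean -0.30 ± 0.11, median 0.00, adjusted p = 0.622), with BIRC5 at 1.40 ± 0.14 and BIRC3 at -2.06 ± 0.34. Of 11 inflammatory genes 1 rose and 5 fell (mean -0.55 ± 0.20, adjusted p = 0.097, and 0.0352 in the unpaired fit, with a range of camera values up to 0.513 over the alternatives), and of 15 interferon response genes 3 fell and 0 rose (mean -0.24 ± 0.08, adjusted p = 0.169), OAS1 among them (-1.02 ± 0.19). Without a replicate the interferon mean reached -0.65 where the filter kept 5 of the members, and lay between -0.26 and -0.20 with all 15. Of 20 DNA replication genes 4 rose and 4 fell (mean 0.02 ± 0.18, adjusted p = 0.69), with RFC2 at 1.29 ± 0.27 and GINS1 at -1.38 ± 0.30. Of 22 mitotic genes 3 rose and 0 fell, or 1 and 0 adjusted over the list alone (mean 0.16 ± 0.41, adjusted p = 0.595). The kinase AURKB rose by 0.84 ± 0.26 but did not pass in the unpaired fit. BUB1 rose by 0.76 ± 0.39 but did not pass without replicate 1 (0.67), 3 (0.69) or 4 (0.73) or under median centring (0.41). The mitotic list stood at -0.38 in pool pair 2 and between 0.07 and 0.52 in the others.

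Markers of other cells of the follicle were tested beside these groups. Oocyte markers had a mean of -0.18 ± 0.33 (15 measured, 1 up, 2 down and none when adjusted over the list alone, camera adjusted p = 0.622), and they stood apart in pool pair 2, at -0.67 against -0.05, -0.00 and -0.01 in pairs 1, 3 and 4. RNF114, the member that passed with the smallest p, fell by 0.44 ± 0.23 and did not pass without replicate 1 (-0.37) or 2 (-0.37). Of 11 fibroblast and smooth muscle markers 3 rose and 4 fell (mean -0.35 ± 0.06, adjusted p = 0.595), with PDGFRA at -2.15 ± 0.50 and ACTA2 at 0.69 ± 0.16, the latter not passing in the unpaired fit. Of 6 endothelial markers 1 fell (mean -0.21 ± 0.04, median 0.00, adjusted p = 0.622): KDR, a VEGF receptor, with a log2 ratio of -1.19 ± 0.27 (adjusted p = 0.00323). It was above the detection level in 0 of 8 adenosine channel values, against 8 of 8 in control. The size of its fall therefore depended on the background (-0.87 without background correction, -3.02 with an offset of 0). Of 9 immune cell markers 1 fell, CD68 (-0.56 ± 0.21), and 0 rose (mean -0.06 ± 0.06, adjusted p = 0.764). Of 5 theca markers 1 rose, ACTA2 (mean 0.17 ± 0.16, adjusted p = 0.755), and of 7 red blood cell markers 1 rose (mean 0.03 ± 0.03, adjusted p = 0.688). Lists that did not pass and for which no second pair of counts is given had the same counts adjusted over the list alone.

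**Figure D3:**
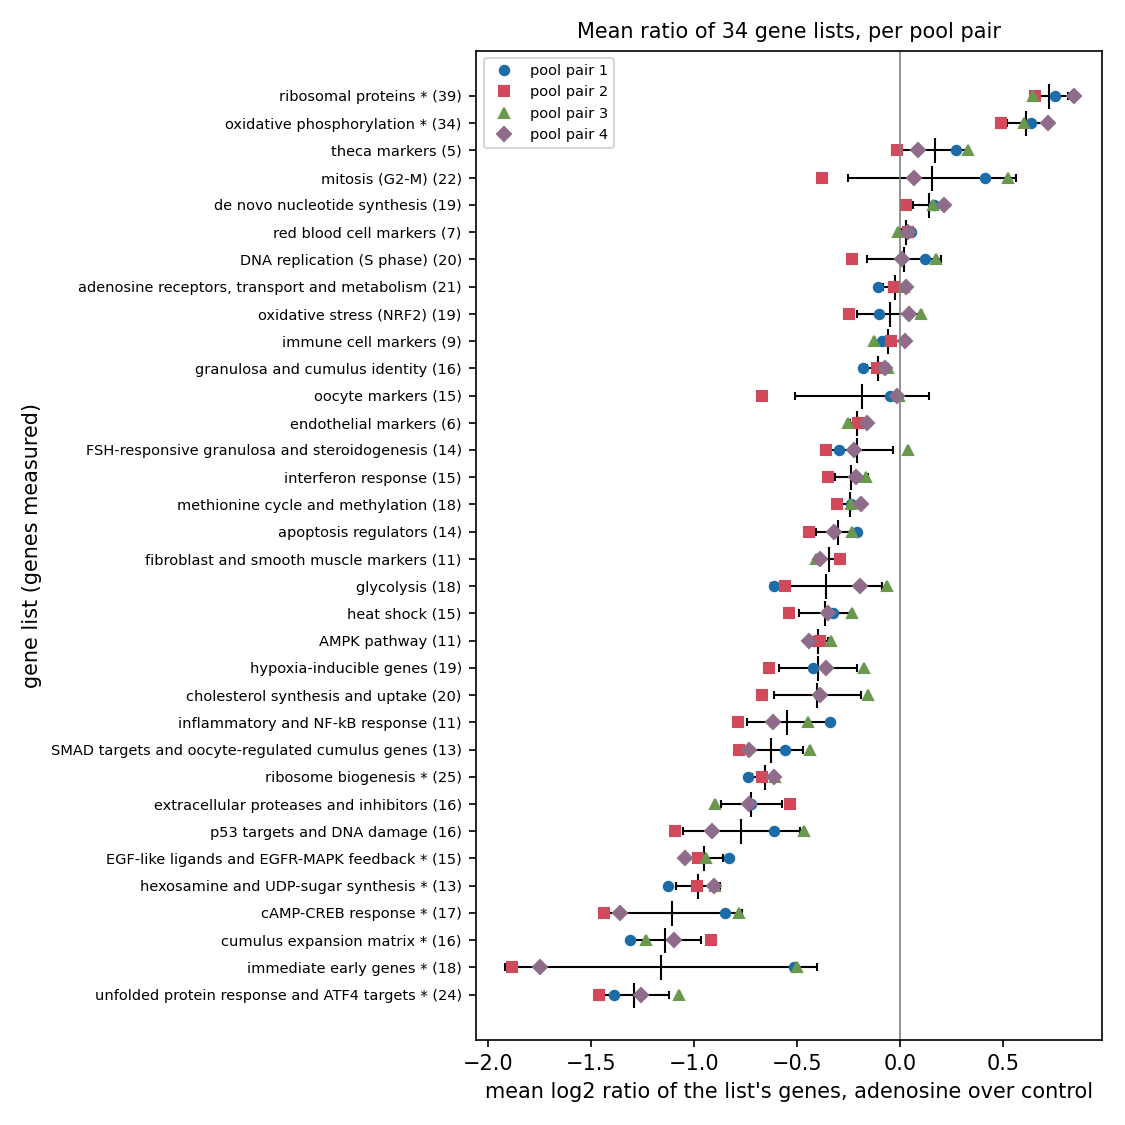
Mean log2 ratio of adenosine over control (x axis) of 34 gene lists (y axis, genes measured in brackets). Coloured symbols are the 4 pool pairs, the black tick and bar their mean and SD, and an asterisk marks an adjusted p under 0.05 in camera with a preset correlation. The means run from 0.72 for ribosomal proteins to -1.29 for the unfolded protein response, and oocyte markers have pool pair 2 apart at -0.67.

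Of the 34 lists, 9 were shifted by camera with a preset correlation, 2 up and 7 down, and 0 passed with an estimated correlation (lowest adjusted p = 0.431, and 1 list with an unadjusted p under 0.05). The interferon list had an estimated correlation of -0.042, below the preset one, and its camera adjusted p still went from 0.169 to 0.489. A failure with an estimated correlation thus does not tell correlated genes from the small number of pool pairs. By fry, which asks whether a list's genes moved on balance in a common direction and compares them with no other genes, 22 lists passed: these 9 and those of glycolysis, hypoxia, AMPK, the methionine cycle, p53, apoptosis, SMAD targets, granulosa and cumulus identity, extracellular proteases, inflammation, interferon, oxidative stress and endothelial markers. Fitted over 8 arrays with a dye term and the pool pair as a random replicate block, 13529 probes and 9 lists were called. The dye term, which includes the slide, passed for 15820 probes. Its median size over all kept probes, passing or not, was 0.06 on the log2 scale.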

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

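The tests of oocyte RNA, of the dyes and of the spiked controls were chosen after the values were seen, and the splits of the samples before. Of 139 lists and named genes, 5 had a pool pair farther from the other 3 than Dixon's criterion allows, and about 6.95 would by chance.

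Oocyte markers stood at -0.67 in pool pair 2 and between -0.05 and -0.00 in the others. In that pair 4 of 15 measured members were at least 2-fold higher in the control pool than in every other control pool: BTG4 (single-channel level 9.59 against at most 6.38), NLRP9 (8.98 against 6.33), FIGLA (8.90 against 6.75) and ZP4 (8.45 against 6.37). With ZAR1L, another oocyte gene, they were the 5 genes with the largest such excess among 12320, all 5 being named after their values were seen, while of the 15 members 7 were detected in every channel of the other control pools, and 0 were in another list. A dye or slide effect is argued against by both orientations of pair 2 (-0.63 and -0.72). The mean of the other pairs was -0.022. It cannot decide whether adenosine lowers these transcripts where they are present, since the 4 genes reached at most 6.75 in the control pools of those pairs. Little was left there to be lowered. Oocyte RNA in control pool 2 may be the source, since these cells were cultured around oocytes, but the other 11 members exceeded the other controls by at most 0.15, and with RNF114 aside their levels reached at most 7.55, against a median of 7.13 over all genes, so whether their probes can register the transcripts stays open.

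The rise of ribosomal protein genes depended on the dye orientation. The 16 dimmer members had means of 0.81 with adenosine in Cy5 and 0.83 with adenosine in Cy3. A dye effect of the same sign on both slides would change sign between these, and is argued against as the source of their rise. The bound of 13 was set after the values were seen, and the dimmer members cannot test an effect confined to bright probes. For the 23 brighter members, with means of 1.44 with adenosine in Cy5 and -0.12 with adenosine in Cy3, a dye effect of equal size in both orientations would cancel, and their mean of 0.66 ± 0.11 (SD over pairs, n = 4) argues against it as the source of the rise. Each orientation lay on 1 slide, so a dye effect that differed between the slides was not tested and stays open for these members. Among all changed probes with a log2 brightness of 13 or more, 71.4% of 294 had the same sign in both orientations, against 97.4% of 11553 dimmer ones.

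Spiked control transcripts of 2 kinds, present as 32 spots each and used in no comparison, had a mean log2 ratio of -1.07 in pool pair 3, against -0.27 to 0.11 in the other pairs, and were below 0 in both orientations of pair 3 (-1.09 and -0.82 for the dimmer, -1.43 and -0.96 for the brighter). The labels do not say at which step they were added.

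Single genes were apart in pool pair 3, with KDM3A at -1.66 against -1.56 to -1.55 and TIMP2 at -3.47 against -2.85 to -2.83. UMPS stood at -1.62 in pair 1 against -1.31 to -1.28, and BIRC5 at 1.62 in pair 2 against 1.32 to 1.34.

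The 4 pool pairs allow 8 sign patterns, too few for a share under 0.05. The real pattern gave 11847 probes, 1 of 8 patterns with as many, and the highest of the others gave 0. For gene lists the real pattern gave 9, as many were reached by 2 of 8 patterns, and the highest other gave 10. In the unpaired fit the real split of the 8 pools gave 7497 probes, which 1 of 35 splits reached, so chance could be excluded only where the pools are taken as exchangeable and the pairing is set aside. The splits that part all 4 pairs number 8, again too few for a share under 0.05. The highest other split, 2975 probes, set pools 1 and 2 of both groups against pools 3 and 4 and so parted 0 of the pairs. All other splits gave 0, including the others that part 4 pairs. Pools 1 and 2 also parted from pools 3 and 4 along the second principal component (29.7% of the variance, after 58.2% for the first, which parted adenosine from control). Both pools of a pair were read from the same arrays, and each replicate number had the same area on both slides. A difference between pools 1 and 2 and pools 3 and 4 thus cannot be told from one between arrays or areas.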

How the results depend on the processing

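The detection level from the median and MAD, the pool pairs 1 and 2 or 3 and 4 alone, leaving out a replicate with the probes kept over all 4 pairs, and the hexosamine list without the hyaluronan synthases, were chosen after the data were seen. Aquantile scaling left every ratio as it was. With all 4 pairs, the settings that moved the count of changed probes by under 1.5 times gave 9004 (strict filter) to 13990 (only adenosine in Cy5). Requiring a 2-fold change as well gave 2465 probes (801 higher, 1664 lower), fewer by construction. Of 14883 probes with an unadjusted p under 0.05 in limma, 5795 also changed by 1.5-fold (2633 higher, 3162 lower). Without the pairing (no replicate block) 7497 were called (3325 higher, 4172 lower), and with the replicate block 13529. The replicate block changed no list call and, of the 105 named genes, only the call of PTX3. Leaving out a replicate gave 7399 to 9469 changed probes, 3571 to 4799 higher and 3828 to 4909 lower, the lowest changed count without replicate 4, with 3 pairs in the fit and 20765 to 31891 probes kept by the filter. With the 31948 probes kept over all pairs it gave 6568 to 9688 changed, 3169 to 4902 higher and 3399 to 4898 lower, again lowest without replicate 4, where 20.6% of the probes were called against 29.2% to 30.3% without another. There 9 of the 98 named genes called with all 4 pairs did not pass: LYSB, LYZ2, TNFAIP6, AREG, FSHR, BUB1, RNF114, SLC7A11 and NHP2. Pool pairs 1 and 2 alone gave 0 probes in limma (9397 at an unadjusted p under 0.05) and pairs 3 and 4 alone 6417 (3377 higher, 3040 lower), with 2 pairs each, and the mean ratios of these sets correlated at 0.933 across probes. Median centring made 38.5% of the calls rises against 50.3%. It sets 1 centre per array, where loess sets a centre at each brightness, so the near-even split of rises and falls depended on the loess step. Which split is nearer to the RNA levels was not tested. Lists with under 5 measured members in a setting were not tested in it. Shifted lists numbered 6 to 11, and 7 to 8 without a replicate, but 0 with an estimated correlation and 22 by fry.

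Of 105 named genes, the mean of kept probes moved 16 by over 1.5-fold, among them UTP15 (-1.24), SRXN1 (-2.76), SLC2A1 (-1.65), TYMS (0.44), BAMBI (-2.59) and OAS1 (-0.38). An offset of 0 moved 18, which were HAS2, AREG, HBEGF, SGK1, RGS2, KDR, C27H8orf4 (-7.20), BMP2 (-7.00), COBLL1 (-6.54), CXCR4 (-6.48), AMIGO2 (-5.89), FOSL1 (-4.45), SPRY2 (-3.95), BAG3 (-2.99), MTHFD2 (-2.68), UMPS (-2.14), PTGS2 (-1.45) and CD68 (-1.19), and each orientation alone 7 (GEM, SLC39A8, NR4A1, INHBA, RPL5, RPL34 and RPL15). The authors' values moved 4 (HAS2, AREG, KDR and SGK1), no background correction 1 (AREG) and median centring 0.

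No called list, and of the named genes no called one but RPL5, at -0.19 with adenosine in Cy3 only, reversed in a planned or added setting. Other genes did: of 11847 changed probes 11460 had the same sign in both orientations, and of the 23 brighter ribosomal protein genes 9 were above 0 in both. Reversals of uncalled values were small. With adenosine in Cy5 only, ADORA1 stood at -0.037, ADORA3 at -0.0092 and the DNA replication list at -0.035. With adenosine in Cy3 only, ADORA2A stood at 0.080, ADORA2B at 0.020, ADA at -0.028 and the adenosine list at 0.0061. The authors' values gave ADORA2B 0.0095, ADA -0.11, the adenosine list 0.035 and the oxidative stress list 0.014, and ADORA2A stood at 0.021 without background correction. Median centring gave nucleotide synthesis -0.11, DNA replication -0.16 and mitosis -0.087, the strict filter DNA replication -0.023, and the mean of kept probes the adenosine list 0.026. Pairs 1 and 2 alone gave DNA replication -0.057 and ADORA2B 0.018, and pairs 3 and 4 alone the adenosine list 0.023, oxidative stress 0.073, ADORA2A 0.024 and ADORA3 -0.034. Without a replicate, the adenosine list ranged from -0.040 to 0.038, DNA replication from -0.038 to 0.10, oxidative stress from -0.10 to 0.014, ADORA2A from -0.063 to 0.0035 and ADORA2B from -0.099 to 0.010, and ADORA3, whose probe the filter on 3 pairs kept only without replicate 3, from -0.016 to 0.038. Dim probes limit what can be seen, since normexp with an offset shrinks ratios near background.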

Other observations

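The tests of gene families, defined by the stem of their symbols, and those on the sizes of rises and falls were chosen after the results were seen. Of 130 families with at least 10 measured genes, 17 passed camera with a preset correlation, 8 up and 9 down, and 0 with an estimated correlation (3 at an unadjusted p under 0.05). Of 31 RBM genes, which bind RNA, 19 fell and 0 rose (mean -0.54 ± 0.11, SD over pairs, n = 4, adjusted p = 0.000237), and 18 of 28 DDX helicases fell and 1 rose (-0.56 ± 0.15, adjusted p = 0.00147). Of 26 MED genes, subunits of the Mediator complex of transcription, 12 fell and 3 rose (-0.41 ± 0.09, adjusted p = 0.041), and of 20 NUP genes of the nuclear pore 8 fell and 1 rose (-0.42 ± 0.18, adjusted p = 0.0468). Of 11 DNAJB co-chaperones 6 fell and 0 rose (-1.08 ± 0.11, adjusted p = 0.0239). COMMD genes rose in 7 of 10 cases and 0 fell (0.54 ± 0.08, adjusted p = 0.0239), as did 8 of 15 aldehyde dehydrogenases (ALDH), with 0 falls (0.42 ± 0.08, adjusted p = 0.0328). Each of these families had the same direction in all 4 pairs and kept it under every normalization run. For all of them the adjusted p = 0.854 with an estimated correlation.

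Falls of over 4-fold outnumbered rises of that size 26.7 to 1 over kept probes. The choice of normalization is argued against as the source, since over 6 ways of normalizing, no normalization included, the fewest falls per rise were 14.5. A shift of all ratios by 0.63 would be needed to even the counts. Between the ways of normalizing, the median difference of a probe's ratio from that reported was largest with no normalization, at -0.23. All of these ways start from the same scans of labelled RNA, and none can show a difference in RNA amount per cell. Whether the centre was set too low thus stays open. A candidate explanation is the loss of short-lived messages when their transcription is lowered, which would also touch genes outside the lists. The zinc finger genes with ZNF symbols, a family known for short-lived messages, had a mean of -0.34 ± 0.03 and a median of -0.15 (77 of 189 fell, 15 rose and 97 did not pass, adjusted p = 0.000237, adjusted p = 0.854 with an estimated correlation). The direction is the one this would predict, but the family was chosen after the results were seen. Shifts of this size do not bear on falls of over 4-fold. No half-life was measured and no sample from before culture is among the arrays, so a loss cannot be told from a smaller rise in culture. A lower response of these genes for another reason stays open.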
